A study of Homo sapiens with 14 samples.

How the data were processed

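RNA from Kasumi-1 cells, an established human acute myeloid leukaemia line that carries the AML1-ETO (RUNX1-RUNX1T1) fusion, was measured on 14 single-colour oligonucleotide arrays. Per the labels, each array was taken 96 h after transfection, or after the same time without it. The labels gave 6 groups. An siRNA against AML1-ETO was delivered by lipid reagent on 3 arrays and by nucleofection, an electrical transfection, on 3 arrays. A control siRNA against firefly luciferase was delivered by lipid on 3 arrays and by nucleofection on 2. One further array came from nucleofection without siRNA and 2 came from untransfected cells. The siRNA concentration was 240 nM with lipid and 1.5 µM with nucleofection, so that dose and method could not be separated. Luciferase nucleofection replicate 3 and untransfected replicate 2 were not analysed here. The labels did not say whether replicates came from separate cultures, and the p-values therefore measure only the spread between these arrays, which may be technical.

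The deposited table held 1 intensity per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The software version and its settings were not given in the sources used here. Per the labels, each array was multiplied by 1 scale factor, which was 1 for untransfected replicate 3. The deposited intensities had a mean of 138.5 on every array, and 100% of them were whole multiples of 0.1 once divided by the scale factor, within 0.02 of a multiple. Replicates were not pooled. Because every array had been set to the same mean, a shift shared by most genes cannot be seen in these values, and a change in a few very bright transcripts moves all others slightly.

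The table held 22283 probe sets. By the platform annotation, 19065 had 1 gene symbol, 1043 had several and 2107 had none, and 68 were control probe sets. Updating the symbols through gene identifiers changed 0 of them. Names were taken only from probe sets with 1 symbol. No probe set had RUNX1 as its only symbol in the annotation used here, and RUNX1 was not analysed here. Probe set names ending in _s_at or _x_at can take signal from related transcripts.

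Intensities below 20 were raised to 20 and log2 was taken, which affected between 38.4% and 44.3% of the probe sets of an array. Differences are on this scale, so those of dim genes are understated. Where all arrays of a group lay at the floor, the difference is given as a bound. Each of 11963 genes was represented by its probe set with the highest mean, and the upper 60% of genes by mean, 7178 genes with a mean signal of at least 26.6, were tested. R 4.3.3 and limma 3.58.1 were used. The functions lmFit and eBayes were fitted to 6 group means over all 14 arrays, which left 8 residual degrees of freedom and a prior of 4.65. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were AML1-ETO against luciferase siRNA as the mean of both methods and within each method, the difference between the methods in that effect, lipid against nucleofection as the mean of both siRNAs, and each luciferase group against untransfected cells. The adjusted p-values below are limma's. RUNX1T1 probe sets were fitted without the filter and adjusted over the 4 probe sets alone. Single measures were compared by exact two-sided permutation tests of 6 against 5 arrays, whose smallest possible p is 0.00216. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

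A set of 27 gene lists for myeloid lineages, cell functions, transfection responses and other cell types was tested with camera at a preset inter-gene correlation of 0.01. Of the 875 listed symbols, 756 were on the array. Camera sets a list against all other genes, and calls with an estimated correlation are given beside. Members past the threshold are counted over all genes tested and adjusted over the list alone.

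The genes named were all probe sets of RUNX1T1 and, for the mean knockdown effect, the 12 largest positive and 12 largest negative differences among called genes with the same sign in both methods and non-overlapping arrays within each. For each list described, up to 4 members with the smallest p were named. For the difference between methods the 5 smallest p were taken. For lipid against nucleofection the 10 largest differences each way with non-overlapping arrays within each siRNA were taken, and for each comparison with untransfected cells the 5 largest each way. The groups, the tests, the filter, the lists, this rule and the alternatives were fixed before the data were examined, except where a choice is said to have come later. The alternatives changed the scaling, the floor, the filter, the features, the variance model, the arrays fitted, the controls, the covariates and single arrays.

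The steps were tested on simulated data for 7178 genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. For the mean knockdown effect, 34% of the smaller and 86% of the larger changes were recovered, with 5 unchanged genes called. The lipid comparison recovered 11% and 66%, with 7 unchanged genes called, and the nucleofection comparison 3% and 49%, with 3. Lipid against nucleofection recovered 30% and 83%, with 9 unchanged genes called, and luciferase nucleofection against untransfected cells 3% and 56%, with 2. In a simulation of the knockdown comparison with 1 list raised, that list and no other was called. Simulated genes were drawn independently, so this did not test lists whose members move together. The number of arrays limits the precision. Within groups, arrays correlated across the tested genes with r between 0.955 and 0.974, and 0 pairs of arrays were identical.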

Results

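Expression was measured in Kasumi-1 cells 96 h after transfection with an siRNA against the AML1-ETO fusion or against luciferase, by lipid reagent or by nucleofection, beside untransfected cells. The groups held 3 and 3 arrays for lipid, 3 and 2 for nucleofection, 1 for nucleofection without siRNA and 2 for untransfected cells. The AML1-ETO siRNA had the sense strand CCUCGAAAUCGUACUGAGA and the antisense strand UCUCAGUACGAUUUCGAGG. Its position in the genome was not analysed here.

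Whether the siRNA lowered its target was read from RUNX1T1, the fusion partner also called ETO. The brightest of the 4 RUNX1T1 probe sets fell by nucleofection from a signal of 704 ± 83.6 (SD, n = 2) with luciferase siRNA to 299 ± 41.7 (SD, n = 3) with AML1-ETO siRNA. By lipid its signal was 556 ± 14.4 (SD, n = 3) with luciferase siRNA and 443 ± 52.9 (SD, n = 3) with AML1-ETO siRNA. Untransfected cells stood at 566 ± 73.9 (SD, n = 2) and the array without siRNA at 582. As the mean of both methods the log2 difference was −0.79 with a standard error of 0.10 (adjusted p = 0.000124, a change of −42.0%). By nucleofection it was −1.24 (adjusted p = 8.22e-05), and by lipid −0.34, which did not pass (adjusted p = 0.0632). The difference between methods was 0.90 (adjusted p = 0.00592).

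**Figure D1:**
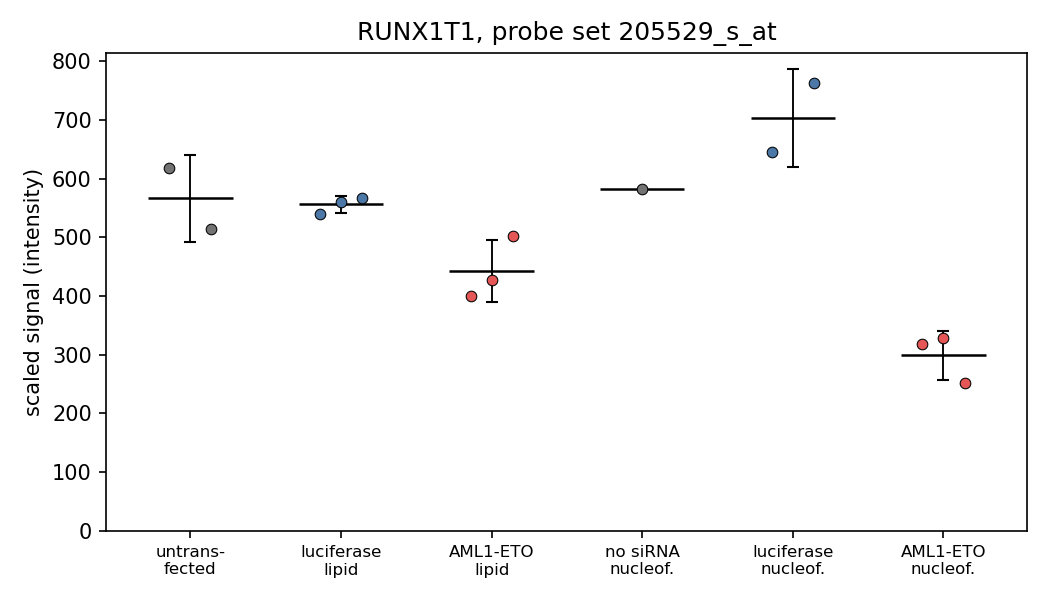
Scaled signal (linear intensity) of the brightest RUNX1T1 probe set for each array by group, with points for arrays, horizontal lines for group means and error bars for SD where a group held more than 1 array. The mean was 299 with AML1-ETO siRNA by nucleofection and 704 with luciferase siRNA, against 443 and 556 by lipid.

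Of the other RUNX1T1 probe sets, the next brightest fell by 0.68 as the mean of both methods (adjusted p = 0.000915). Its difference was −1.08 by nucleofection and −0.29 by lipid (adjusted p = 0.000625 and 0.181), and these differed from each other by 0.79 (adjusted p = 0.0314). The dimmest probe set was at −0.91 (adjusted p = 0.000144), and its lipid difference was −0.72 (adjusted p = 0.0094). Its nucleofection arrays with AML1-ETO siRNA had a mean signal of 11.2, under the floor, so the mean and its nucleofection difference of −1.10 are bounds, and its call was lost with a floor at 64. The remaining probe set did not pass, at −0.22 (adjusted p = 0.12). These probe sets do not separate the fusion from RUNX1T1's own transcript.

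The main question was which genes changed when AML1-ETO was targeted, as the mean of both methods. Among probe sets with 1 gene symbol, genes of granule proteins rose the most. CTSG, which encodes the neutrophil protease cathepsin G, rose by 2.54 on the log2 scale (SE 0.12, adjusted p = 1.68e-07). By lipid its geometric mean signal was 1199 with luciferase siRNA and 2998 with AML1-ETO siRNA, and by nucleofection it was 421 and 5717. CST7, an inhibitor of cysteine proteases, rose by 2.42 (SE 0.15), and SRGN, the core protein of a granule proteoglycan, by 2.09 (SE 0.13). The luciferase nucleofection arrays of CST7 had signals of 20.5 and 8.71, near or under the floor, and its rise ranged from 1.30 to 2.72 under alternatives. MS4A3, a membrane protein of myeloid precursors, lay at the floor on all luciferase and untransfected arrays and was at least 6.22-fold higher by lipid, with adjusted p = 3.24e-05 for the mean of both methods.

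The other genes with the largest rises also included markers of mature myeloid cells. IGFBP7, a secreted growth factor binding protein, rose by 2.06 and CD24, a surface glycoprotein, by 1.99. SELPLG, the ligand of P-selectin, rose by 1.67, as did TYROBP, a signalling adaptor of myeloid cells. S100A8, a calcium-binding protein of neutrophils and monocytes, rose by 1.56, RNASE2, a granule ribonuclease, by 1.44, and the adhesion molecule CEACAM6 by 1.39. LAPTM5, a lysosomal membrane protein of blood cells, rose by 1.31, with geometric mean signals of 955 and 1644 by lipid and 713 and 2527 by nucleofection. The adjusted p of these 12 genes was at most 0.00334. All 12 were higher on every AML1-ETO array than on any luciferase array of the same method, which the rule for naming them required.

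**Figure D2:**
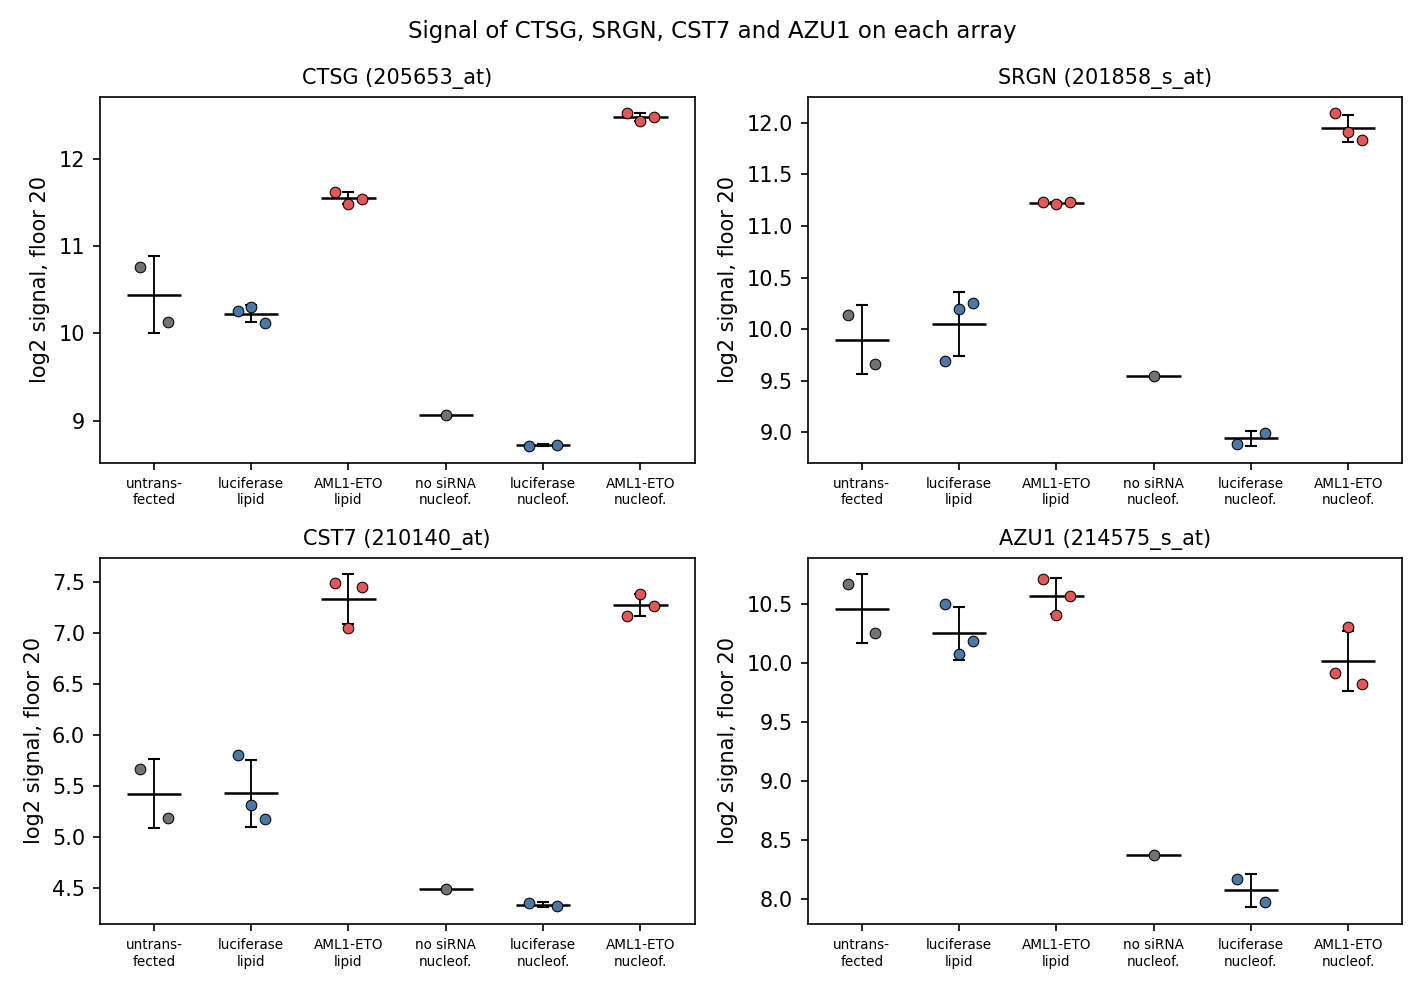
Log2 signal, floored at 20, of CTSG, SRGN, CST7 and AZU1 for each array by group, with points for arrays, horizontal lines for group means and error bars for SD where a group held more than 1 array. The y axes are on a log2 scale and do not start at 0. CTSG had a geometric mean signal of 5717 with AML1-ETO siRNA by nucleofection and 421 with luciferase siRNA, against 1393 in untransfected cells.

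The largest fall among the called genes was that of CXCL8, a neutrophil-attracting chemokine, by 1.31 (SE 0.18, adjusted p = 0.00265). Its geometric mean signal by nucleofection was 794 with luciferase and 159 with AML1-ETO siRNA. By lipid it was 855 and 695, a difference that did not pass (adjusted p = 0.999). Among genes with non-overlapping arrays within each method the largest falls were smaller. FSCN1, which encodes an actin-bundling protein, fell by 0.93 (SE 0.14, adjusted p = 0.00334) and NFIC, a transcription factor, was at −0.94 (SE 0.14, adjusted p = 0.00374). FSCN3 was at −0.97, ARHGAP44 at −0.93, the cohesin subunit SMC3 at −0.80 and the scaffold protein CASK at −0.71. The transcription factor TFAP4 and BEX1 were at −0.69. ATN1, ENAH and STOML1 were each at −0.67, a bound for STOML1, whose AML1-ETO arrays by lipid were all at the floor. Other probe sets were at −0.48 (SE 0.20) for FSCN1, −0.40 (SE 0.21) for NFIC, −0.29 and −0.07 for SMC3, −0.23 and −0.18 for ATN1 and 0.03 for STOML1. The adjusted p of these genes lay between 0.00334 and 0.048. RUNX1T1 itself was the remaining gene of this group. BEX1 lost its call under 21 of 24 alternatives, TFAP4 under 18 of 25, with 1 reversed, FSCN3 and CASK under 17 of 25, ENAH under 16 of 25, STOML1 under 15 of 24, ARHGAP44 under 11 of 24, ATN1 under 10 of 26 and SMC3 under 6 of 26, against 1 of 25 for FSCN1 and 0 of 25 for NFIC.

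In all, 119 genes were called for knockdown, mean of both transfection methods, 82 higher and 37 lower (68.9% higher), among 1031 with an unadjusted p below 0.05 where chance gives 359. With quantile normalization 149 were higher and 36 lower (80.5%), and with arrays centred on their medians 129 were higher and 34 lower (79.1%). Of the 119 genes, 72 had non-overlapping arrays within both methods, which chance gives for 1% of unchanged genes, though the 119 had been called on these same arrays. With the untransfected arrays and the array without siRNA as controls 71 genes were called, 63 higher and 8 lower, and 48 of these were among the 119. Leaving out single arrays gave 59 to 66 genes without 1 of the 5 luciferase arrays, 67 without AML1-ETO lipid replicate 1, 73 without AML1-ETO nucleofection replicate 1 or 3, and at most 102 otherwise.

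Among the lists, granule proteins rose in 7 of the 12 measured members, and 8 passed adjusted over the list alone (camera adjusted p = 1.94e-21, and adjusted p = 0.00137 with an estimated correlation). Besides CTSG, CST7, SRGN, MS4A3 and RNASE2, AZU1, an antimicrobial granule protein, rose by 1.13 and ELANE, neutrophil elastase, by 0.56. The other 5 members did not pass. They were CD63 at 0.35, MPO at 0.19, PRTN3 at 0.17, CTSC at 0.05 and MMP9 at −0.25, and ELANE and these were named after their values were seen.

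Neutrophil maturation genes rose in 4 of 18 members, and in 7 adjusted over the list alone (adjusted p = 6.37e-10, and adjusted p = 0.00342 with an estimated correlation). They were CEACAM6, SELPLG, FUT4 at 0.57 and the transcription factor CEBPE at 0.59. Monocyte and macrophage genes rose in 4 of 15 members, TYROBP, S100A8, LST1 at 1.10 and AIF1 at 1.02, and adjusted over the list alone 8 rose and 2 fell (adjusted p = 6.95e-07, and adjusted p = 0.00937 with an estimated correlation). Lysosomal genes rose in 4 of 32 members, FUCA1 at 0.84, CTSD at 0.60, LAMP2 at 0.59 and NPC2 at 0.47, and in 6 adjusted over the list alone. That list passed with the preset correlation (adjusted p = 3.41e-07) and not with an estimated one (adjusted p = 0.236). Relative to untransfected cells, CTSD was higher with AML1-ETO siRNA by nucleofection, at 1.04 (adjusted p = 0.00441), while FUCA1 at 0.35, LAMP2 at −0.14 and NPC2 at −0.33 did not pass. With luciferase siRNA by nucleofection FUCA1 (adjusted p = 0.0401), LAMP2 at −0.90 and NPC2 at −1.09 were lower than in untransfected cells.

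In 3 further lists 0 members passed over all genes tested, and their calls were lost with an estimated correlation. The 40 ribosomal protein genes stood higher than other genes, with a median of 0.09 (adjusted p = 4.69e-05, and adjusted p = 0.56 with an estimated correlation). That call was also lost with quantile normalization (adjusted p = 0.329). The 32 genes of ribosome biogenesis and MYC targets stood lower, with a median of −0.18 (adjusted p = 0.00069, and adjusted p = 0.236 with an estimated correlation), and adjusted over the list alone 2 fell. DDX21, with a difference of −0.52, had the smallest p (adjusted p = 0.061). The 39 S phase genes stood lower, with a median of −0.16 (adjusted p = 0.0343, and adjusted p = 0.681 with an estimated correlation), and 0 passed adjusted over the list alone.

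The other 20 lists were not called. Adjusted p was 0.0509 for the lists of unfolded protein and amino acid stress, of mast cells, eosinophils and basophils, of immediate early genes and of mitosis. It was 0.0512 for heat shock, 0.0683 for lymphoid, 0.116 for glycolysis and hypoxia and 0.376 for erythroid and megakaryocytic genes. It was 0.522 for markers of cells outside the blood and for the siRNA machinery, 0.538 for oxidative phosphorylation, and 0.633 for inflammatory and for p53 and cell cycle inhibitor genes. It was 0.797 for apoptosis regulators and MHC class II, 0.825 for cholesterol synthesis, and 0.994 for interferon response, histone, stem and progenitor and AML1-ETO signature genes. The last of these held IGFBP7, which rose, and RUNX1T1, which fell, while 11 of its 13 members did not pass. All 18 stem and progenitor members, ERG at −0.39 and SPI1 at 0.32 among them, did not pass. Some of these 20 lists were called under alternatives, heat shock under 9, unfolded protein and amino acid stress under 8, and mitosis and the mast cell list under 7 each. Immediate early genes were called under 6 and lymphoid genes under 2. The median of all tested genes was −0.07. The test direction was upward for the apoptosis, p53, MHC class II and stem lists although their medians and means lay below 0. For the glycolysis, histone, lymphoid, AML1-ETO signature and outside-blood lists the median and mean differed in sign.

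Whether the response was the same by both methods was read from each method alone. By nucleofection the largest rises were again in granule and myeloid genes, with CTSG at 3.76, CD24 at 3.05, SRGN at 3.00 and CST7 at 2.94. By lipid CTSG rose by 1.32, SRGN by 1.17 and CST7 by 1.90, while CD24 was at 0.93 and did not pass (adjusted p = 0.213). MS4A3 rose by at least 2.64 by lipid and at least 1.49 by nucleofection, and S100A8 by 1.73 and 1.40, and neither difference between methods passed (adjusted p = 0.319 and 0.792). The granule list was called by each method, with 8 of 12 members higher by nucleofection, 9 adjusted over the list alone (adjusted p = 3.3e-18, and adjusted p = 0.00246 with an estimated correlation) and 4 by lipid, 5 adjusted over the list alone (adjusted p = 3.77e-13, and adjusted p = 0.00766 with an estimated correlation).

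For knockdown by nucleofection 188 genes were called, 117 higher and 71 lower (62.2%). With quantile normalization 257 were higher and 116 lower (68.9%), and with arrays centred on their medians 211 were higher and 71 lower (74.8%). The median of all genes was −0.11. By lipid 9 genes were called, against 325 with an unadjusted p below 0.05 where chance gives 359. They were CST7, CTSG, IGFBP7, MS4A3, S100A8, SRGN, TYROBP, NFIC at −1.23 and MTARC1 at 1.42, and all but NFIC were higher. MTARC1, named after its value was seen, was at −0.32 by nucleofection. The 7 genes called by both methods were all higher, where independent lists would share 0.24. Across all genes, which are not independent replicates, the differences by lipid and by nucleofection correlated with Pearson's r of 0.17 and Spearman's rho of 0.09.

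Of the 119 genes called for the mean, 109 differed more by nucleofection, and the median size was 1.03 by nucleofection and 0.40 by lipid. The count for knockdown by nucleofection fell to 52 and 57 without luciferase nucleofection replicate 1 or 2, and to 94, 120 and 80 without AML1-ETO nucleofection replicate 1, 2 or 3. Fitted on the nucleofection arrays alone it was 23, and with a floor at 64 it was 313, with 129 higher and 184 lower. The lipid count was 4 without luciferase lipid replicate 1 or AML1-ETO lipid replicate 3, and 5 without luciferase lipid replicate 3. Within nucleofection the log2 3′ to 5′ ratio of GAPDH, a sign of RNA or target quality, was −0.14 with AML1-ETO and 0.14 with luciferase siRNA (exact p = 0.1, the smallest possible with 3 against 2 arrays). The ribosomal RNA signal differed by −0.97 on the log2 scale (exact p = 0.5).

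**Figure D3:**
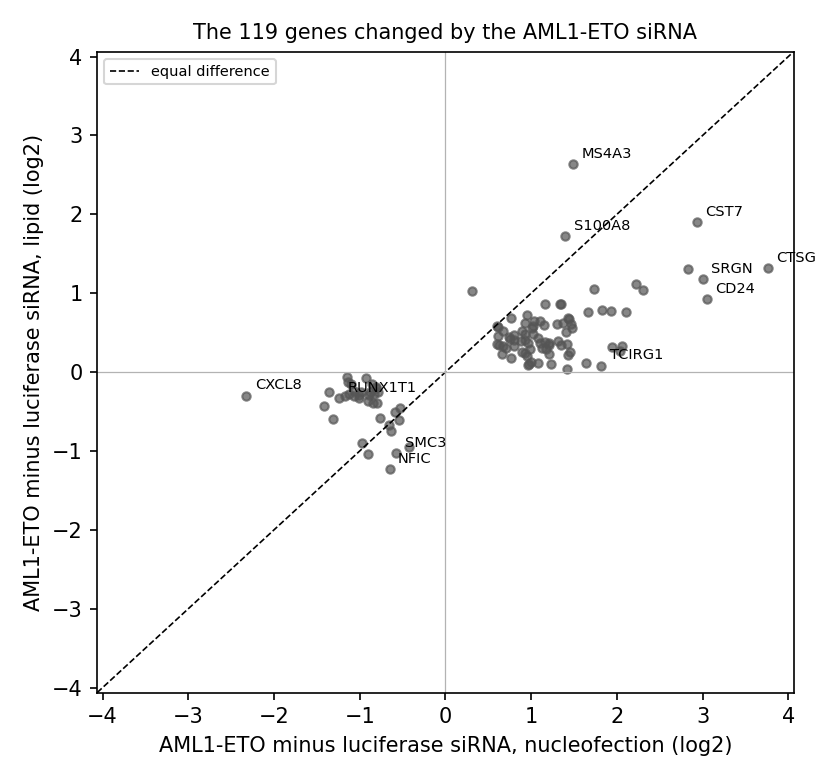
AML1-ETO minus luciferase siRNA on the log2 scale for the 119 genes called for the mean of both methods, with nucleofection on the x axis, lipid on the y axis, 1 point per gene and a dashed line of equal differences. Most points lie closer to 0 by lipid, with a median size of 0.40 against 1.03 by nucleofection.

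The difference between the methods was itself tested. The granule genes CTSG and SRGN differed by less with lipid than with nucleofection, at −2.44 (SE 0.24, adjusted p = 0.00109) and −1.83 (adjusted p = 0.0204). CD24, at −2.12 (adjusted p = 0.0204), and TCIRG1, a subunit of the lysosomal proton pump, at −1.74 (adjusted p = 0.0191), also differed. Relative to untransfected cells TCIRG1 was at 0.15 with AML1-ETO siRNA by nucleofection (adjusted p = 0.61) and at 0.01 by lipid, and neither passed. On the single array of nucleofection without siRNA TCIRG1 was at −1.65. NINJ2 had the next smallest p, at −1.38 (adjusted p = 0.0598), and did not pass. CTSG, SRGN, CD24 and TCIRG1 were the 4 genes called, all with a smaller effect by lipid, among 772 with an unadjusted p below 0.05. The granule list differed between methods, with 2 of 12 members past the threshold and, adjusted over the list alone, 7 with a smaller and 1 with a larger difference by lipid (adjusted p = 5.61e-09, and adjusted p = 0.0267 with an estimated correlation). The lysosomal list (adjusted p = 2.33e-06) and the neutrophil maturation list (adjusted p = 0.00601) did so only with the preset correlation, with adjusted p = 0.537 and 0.167 with an estimated one. CTSG passed under all 24 alternatives, while CD24, SRGN and TCIRG1 lost their calls under 8 or 9. With all arrays kept, the count ranged from 2 with the replicate number as a block to 48 without the filter. It was 1 without luciferase lipid replicate 2 or 3, luciferase nucleofection replicate 1 or AML1-ETO nucleofection replicate 1 or 2. It was 2 without luciferase nucleofection replicate 2 or AML1-ETO lipid replicate 2, and 8 without AML1-ETO lipid replicate 3.

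Lipid and nucleofection were compared as the mean of both siRNAs, 6 arrays against 5. FBN2, a component of extracellular microfibrils, was 4.41-fold higher by lipid (log2 2.14, SE 0.12, adjusted p = 1.46e-06). MRPL35, a mitochondrial ribosomal protein, was higher by 1.72, EGFL7 by at least 1.70, SPINT2, a protease inhibitor, by 1.64, and SLC39A4, a zinc transporter, by 1.53. NPIPA1 and EPHX1, an epoxide hydrolase, were each higher by 1.52. CFD, complement factor D, was higher by 1.51, EID1 by 1.50 and ABCA1, a cholesterol exporter, by 1.49. Relative to lipid, nucleofection arrays were brighter for USF2 at −1.68, GIT2 at −1.57, RC3H1 at −1.49, SMC3 at −1.45, NFIC at −1.41 and PTPRC, the leukocyte antigen CD45, at −1.38. They were also brighter for RASSF4 at −1.36, RCC1 at −1.14, MRC2 at −1.12 and RSPH6A at −1.12, a bound. Other probe sets did not show these differences throughout. They were at −0.03 and 0.04 for SMC3, −0.57 and 0.17 for PTPRC, −0.92 and 0.07 for USF2, 2.10 and −0.04 for ABCA1, 0.72 for RASSF4, 0.24 for MRC2, 0.01 for GIT2 and −0.34 for RCC1, and that of FBN2 lay at the floor. The largest adjusted p of these 20 genes was 0.00202, and none changed sign under quantile normalization or median centring.

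Of 22 genes of cholesterol and fatty acid synthesis 11 were higher by lipid and 1 lower, led by FASN at 1.39, TM7SF2 at 1.16, SCD at 0.93 and SQLE at 0.85. Of 40 ribosomal protein genes 17 were lower by lipid and 1 higher, with RPL32 at −0.64, RPS18 at −0.61, RPS24 at −0.56 and RPS10 at −0.55, though with quantile normalization these 4 did not pass and RPS10 turned to 0.01. Of 18 stem and progenitor genes 8 were higher by lipid, led by SPI1 at 0.82, HHEX at 0.78, ERG at 0.69 and LMO2 at 0.60. Of 15 monocyte and macrophage genes 2 were lower by lipid, TYROBP at −0.68 and IRF8 at −0.47. TYROBP rose with AML1-ETO siRNA by 1.11 by lipid and by 2.23 by nucleofection, so its mean over both siRNAs also holds that response. Adjusted over the list alone, 12 were higher and 1 lower for cholesterol synthesis, 21 lower and 1 higher for ribosomal proteins, 9 higher for stem and progenitor genes and 1 lower for monocyte genes. With the preset correlation these 4 lists were called at adjusted p = 0.0404, 2.89e-16, 0.0491 and 0.0273, and with an estimated correlation none was (adjusted p = 0.513 for each). With quantile normalization none of them was called, at adjusted p = 0.125, 0.662, 0.0571 and 0.0571, though their directions stayed.

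For lipid against nucleofection, mean of both siRNAs, 1841 genes were called, 1577 higher by lipid and 264 lower (85.7%), and the median of all genes was 0.17. With quantile normalization 633 were higher and 499 lower (55.9%), and with arrays centred on their medians 711 were higher and 607 lower (53.9%). The ribosomal RNA control probe sets, which are no part of the tested genes, moved with the method. Their mean log2 signal was 8.23 ± 1.19 (SD) on the 5 nucleofection and 5.56 ± 0.61 (SD) on the 6 lipid arrays (exact p = 0.00216, the smallest possible). The log2 3′ to 5′ ratio of GAPDH was −0.03 ± 0.17 (SD) by nucleofection and −0.27 ± 0.07 (SD) by lipid (exact p = 0.00433), while that of ACTB was 0.48 and 0.41 (exact p = 0.604). Between siRNAs the exact p was 0.764 for ribosomal RNA, 0.405 for GAPDH and 0.874 for ACTB. Over the 10 comparisons of array measures between methods or siRNAs, the adjusted p was 0.0144 for ribosomal RNA and GAPDH between methods. With the ribosomal RNA signal as a covariate, an alternative chosen after seeing the data, 18 genes differed between the methods. Without luciferase nucleofection replicate 1 the count was 1171.

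**Figure D4:**
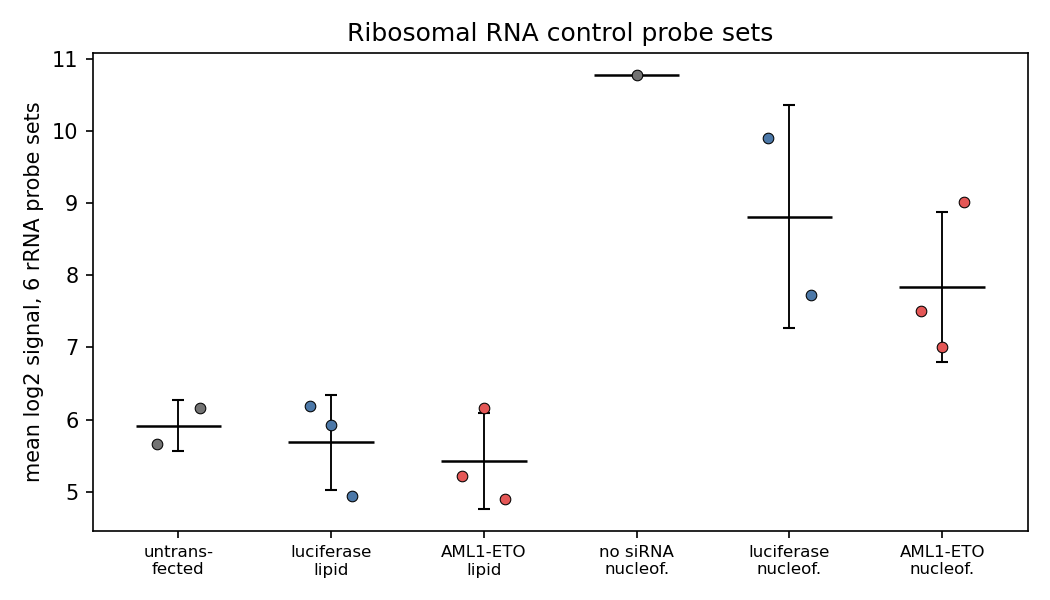
Mean log2 signal of 6 ribosomal RNA control probe sets for each array by group, with points for arrays, horizontal lines for group means and error bars for SD where a group held more than 1 array. The y axis is on a log2 scale and does not start at 0. Lipid and untransfected arrays lay between 4.89 and 6.19, and nucleofection arrays between 7.01 and 10.8, the highest being the array without siRNA.

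The effect of transfection itself was read from the luciferase groups against untransfected cells. By nucleofection the granule genes AZU1, at −2.39, CTSG, at −1.73, and PRTN3, at −1.19, fell. FBN2 at −2.39, MRPL35 at −2.29, CD24 at −2.27 and CFD at −2.13 fell too. BATF3, a transcription factor, rose by 2.04, SLC28A1, a nucleoside transporter, by 1.70, RC3H1 by 1.68, the kinase FGR by 1.66 and THRB, a thyroid hormone receptor, by 1.60. Of these 5, BATF3, SLC28A1 and THRB had untransfected arrays all at the floor, so that their rises are bounds. FGR lost its call under 11 of 16 alternatives, SLC28A1 under 10, BATF3 under 9, THRB under 6 and RC3H1 under 2. Among the falls, MRPL35 lost its call under 4 of 16, FBN2 under 1 of 16, and AZU1, CD24 and CFD each under 1 of 17. Of the 12 granule genes 8 fell, and 9 adjusted over the list alone (adjusted p = 1.89e-06, and adjusted p = 0.0724 with an estimated correlation). Lysosomal genes fell in 7 of 32 and cholesterol synthesis genes in 5 of 22, and adjusted over the list alone in 11, with 1 higher, and in 7. Their adjusted p was 0.00832 and 0.0456, and adjusted p = 0.719 for each with an estimated correlation. The 40 ribosomal protein genes stood higher with a median of 0.14 and 0 members past the threshold (adjusted p = 0.00832, and adjusted p = 0.823 with an estimated correlation). Array quality also differed here. The mean log2 ribosomal RNA signal was 9.90 and 7.72 on the luciferase nucleofection arrays and 5.67 and 6.17 on the untransfected arrays. The log2 3′ to 5′ ratio of GAPDH was 0.25 and 0.03 against −0.19 and −0.21, while the ratios of ACTB overlapped.

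For luciferase siRNA by nucleofection against untransfected cells 369 genes were called, 89 higher and 280 lower (24.1% higher). With quantile normalization 122 were higher and 217 lower (36.0%), and with arrays centred on their medians 139 were higher and 270 lower (34.0%). Without luciferase replicate 1 or 2 the count was 156 or 126, and without untransfected replicate 1 or 3 it was 56 or 155. It was 0 when only these 4 arrays were fitted. By lipid limma called 0 genes, with 267 at an unadjusted p below 0.05 where chance gives 359. It called 1 gene without untransfected replicate 3, with all probe sets, or with a floor at 1. The lists of ribosomal proteins, oxidative phosphorylation and granule proteins stood lower (adjusted p = 2.02e-06, 8.94e-05 and 0.0476) with 0 members past the threshold, and with an estimated correlation adjusted p = 0.968, 0.968 and 0.78. The difference between the luciferase groups was tested directly. There 586 genes were called, 505 higher by lipid and 81 lower. They included 294 of the 369, and the arrays of luciferase nucleofection enter both comparisons.

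Against untransfected cells the AML1-ETO siRNA by nucleofection raised 11 of the 12 genes named for their rises, such as TYROBP by at least 2.44, SRGN by 2.05, CTSG by 2.04 and CST7 by 1.85. CD24, at 0.78, did not pass (adjusted p = 0.0508). By lipid 6 of the 12 passed, CTSG, CST7, SRGN, MS4A3, TYROBP and S100A8, while IGFBP7, CD24, SELPLG, RNASE2, CEACAM6 and LAPTM5 did not (adjusted p between 0.166 and 0.704). Of other genes named in the granule, neutrophil and monocyte lists, LST1 at 1.14 and AIF1 at 1.19 were higher by nucleofection than in untransfected cells, while AZU1 at −0.44 (adjusted p = 0.187), FUT4 at −0.06 and CEBPE at 0.28 did not pass. By lipid AZU1 was at 0.11 and did not pass (adjusted p = 0.998). CXCL8, whose arrays overlapped within a method, was at −2.41 by nucleofection (adjusted p = 0.00044) and at −0.28 by lipid (adjusted p = 0.998). Of the 12 falls named with non-overlapping arrays, 5 were lower than in untransfected cells by nucleofection. They were ENAH at −1.47, ATN1 at −1.28, FSCN1 at −1.11, TFAP4 at −1.07 and RUNX1T1 at −0.92. The other 7 did not pass, with CASK at −0.32, FSCN3 at −0.28, STOML1 at −0.17, ARHGAP44 at 0.18, NFIC at 0.26, SMC3 at 0.29 and BEX1 at 0.41. Of these 7, NFIC was higher with luciferase siRNA by nucleofection than in untransfected cells, at 0.91 (adjusted p = 0.0401). By lipid NFIC at −1.44 and SMC3 at −1.39 were lower than in untransfected cells, and the other 10 did not pass. The median of the 12 granule genes, relative to untransfected cells, was −0.12 with luciferase and 0.23 with AML1-ETO siRNA by lipid. By nucleofection it was −0.85 and 0.08, and with AML1-ETO siRNA 5 of the genes were higher and 2 lower. The median of the 32 lysosomal genes by nucleofection was −0.33 with luciferase and −0.09 with AML1-ETO siRNA. On the single array of nucleofection without siRNA, which has no replicate check, CTSG stood at −1.38 and AZU1 at −2.09 relative to untransfected cells on the log2 scale. Of the 5 genes lower by nucleofection, that array had TFAP4 at −2.09, ENAH at −1.16, ATN1 at −1.06, FSCN1 at −0.39 and RUNX1T1 at 0.04. The falls of TFAP4, ENAH and ATN1 below untransfected cells were thus also seen without siRNA.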

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

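The tests that weigh explanations here, namely the ribosomal RNA covariate, the comparisons and simulations with untransfected cells and the signal before scaling, were chosen after the results were seen.

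The effect of the AML1-ETO siRNA differed between lipid and nucleofection, by a test of the difference itself, in 4 genes, 2 RUNX1T1 probe sets and 3 lists. The log2 differences were −2.44 for CTSG, −1.83 for SRGN, −2.12 for CD24 and −1.74 for TCIRG1. They were 0.90 for the brightest RUNX1T1 probe set and 0.79 for the next brightest. Relative to untransfected cells TCIRG1 did not pass with AML1-ETO siRNA by either method. Adjusted p was 5.61e-09 for the granule list, 2.33e-06 for the lysosomal list and 0.00601 for the neutrophil maturation list, and with an estimated correlation adjusted p = 0.0267, 0.537 and 0.167.

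More genes changed by nucleofection, 188, than by lipid, 9. The ribosomal RNA signal is argued against as the whole cause, since with it as a covariate 124 genes were called by nucleofection and 8 by lipid, and the median size over the 188 genes went from 0.98 to 0.96 with a median SE of 0.19 and 0.20. A fall of the luciferase arrays alone was weighed for the 117 genes higher by nucleofection. Of these, 39 (33.3%) were also higher than in untransfected cells, where independent lists share 2.02 genes. Both comparisons share the AML1-ETO arrays. Simulations of unchanged groups, at the unadjusted p that the observed calls reached and with the same arrays shared, gave 14.7%. The exact binomial upper limit of 18.1% is for 509 genes pooled over 100 simulations, and does not give the spread for 1 data set. At an unadjusted p below 0.05 the share of 24.1% lay within simulations of unchanged groups, with a mean of 18.3% and up to 25.6%. That looser threshold therefore cannot decide. Further simulations set the AML1-ETO arrays equal to untransfected cells and lowered the luciferase arrays by the observed difference. There the share at the p of the observed calls had a mean of 0.16% and was at most 1.98%. The comparison with untransfected cells holds no luciferase array. These values argue against a fall of the luciferase arrays alone for the 39 genes as a set, though not for each of them. For the other 78 genes such a fall cannot be told apart from an effect of the siRNA. Of these 78, 43 were lower in the luciferase arrays than in untransfected cells, where independent lists share 3.04. At an unadjusted p below 0.05 the share over the 477 genes higher by nucleofection at that p was 61.6%. It had a mean of 26.3% and was at most 33.9% in simulations of unchanged groups. Part of the excess, though not all of it in these simulations, may therefore come from the shared arrays. A weaker knockdown by lipid remains a candidate explanation, with RUNX1T1 differing by 0.90 between methods, and the delivery method and the siRNA concentration stay open, as untested.

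Signal appeared outside the tested genes in the ribosomal RNA control probe sets, which were 6.38-fold brighter on nucleofection than on lipid arrays. Larger scale factors are argued against as the whole cause, since before scaling the signal was still 4.49-fold higher (exact p = 0.00216, the smallest possible). Degraded RNA cannot be told apart, because the 3′ to 5′ ratio differed for GAPDH (exact p = 0.00433) and did not pass for ACTB (exact p = 0.604). The delivery method itself could also be a source and was not tested.

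Of 1650 probe sets without a single gene symbol, among 13329 probe sets tested, 15 changed with the AML1-ETO siRNA, 12 higher and 3 lower. The largest of these rises was at least 3.87 (adjusted p = 2.72e-07) and the next 2.11 (adjusted p = 0.00068).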

How the results depend on the processing

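The ribosomal RNA covariate was chosen after seeing the data. The fit without the no-siRNA array and median centring for the method lists were not planned either, and the other alternatives were fixed before. For the mean knockdown effect 28 results were followed, namely the named genes, RUNX1T1 among them, and each RUNX1T1 probe set separately. RUNX1T1 thus enters several times, and its probe sets, adjusted over themselves alone, each kept 15 or 16 of 16 values. Of all 670 values under alternatives, 533 kept direction and side of the threshold, 135 no longer passed, 1 newly passed and 1 reversed. The value that newly passed was that of the RUNX1T1 probe set at −0.22. TFAP4 turned to 0.17 (adjusted p = 0.853) with untransfected and no-siRNA arrays as controls, and its adjusted p ranged from 0.0308 to 0.853. For lipid against nucleofection, 476 of 490 values over 20 genes were kept and 14 no longer passed. For luciferase nucleofection against untransfected cells it was 117 of 163 over 10 genes, with 46 no longer passing. For the difference between methods it was 85 of 119 over 5 genes, with 26 no longer passing and 8 newly passing. Signal near the floor limited the dim genes, and 5606 of the 7178 genes had a value with a floor at 64. The cause was not tested unless the setting itself has fewer genes or arrays.

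Counts that moved by over 1.5 times were as follows. Quantile normalization gave 185 genes for knockdown, mean of both transfection methods, 373 for knockdown by nucleofection, 10 for the difference between methods in the knockdown effect, 1132 for lipid against nucleofection, mean of both siRNAs, and 1 list for the methods. Median centring gave 9 genes for the difference between methods. A floor at 1 gave 7 for that difference and 1 for luciferase lipid against untransfected cells, and a floor at 64 gave 313 by nucleofection and 30 for the difference. Without the filter there were 3 genes by lipid, 295 by nucleofection, 48 for the difference and 12 knockdown lists, and with the upper 30% of genes 5 by lipid and 12 for the difference. All probe sets gave 7 for the difference, 3007 for the methods, 1 for luciferase lipid and 650 for luciferase siRNA by nucleofection against untransfected cells. Trend and robust variance gave 21 for the difference and 563 for luciferase nucleofection, and array weights gave 8 for the difference. The scale factor as covariate gave 544 for the methods, 100 for luciferase nucleofection and 11 knockdown lists. The ribosomal RNA covariate gave 124 by nucleofection, 18 for the methods, and 11 knockdown and 2 method lists. Fitting only the groups compared gave 5 by lipid, 23 by nucleofection, 8 for the difference and 0 for luciferase nucleofection. Untransfected and no-siRNA controls gave 71 for the mean knockdown effect. An estimated inter-gene correlation left 3 knockdown and 0 method lists, and fry called 16 method lists.

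With the replicate number as a block, 73 genes were called for the mean knockdown effect, 5 by lipid, 108 by nucleofection, 2 for the difference between methods and 133 for luciferase nucleofection. The numbers were not taken to pair the arrays, because residual correlations of the 22 same-number pairs lay between −0.29 and 0.05, with 0 above 0.1.

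Leaving out 1 array at a time gave 59 to 102 genes for the mean knockdown effect, 4 to 7 by lipid, 52 to 120 by nucleofection, 1 to 8 for the difference, 1171 to 1828 for the methods, 0 to 1 for luciferase lipid and 56 to 156 for luciferase nucleofection. It gave 3 to 4 RUNX1T1 probe sets, 6 to 11 knockdown lists and 1 to 5 method lists. Knockdown lists numbered 11 without luciferase lipid replicate 1 or AML1-ETO lipid replicate 3. Method lists numbered 2 without luciferase lipid replicate 1, luciferase nucleofection replicate 1 or AML1-ETO nucleofection replicate 2, and 1 without AML1-ETO lipid replicate 2 or AML1-ETO nucleofection replicate 3. The log2 3′ to 5′ ratio differed between siRNAs by −0.14 to −0.01 for GAPDH and −0.06 to 0.08 for ACTB, and between methods by −0.28 to −0.18 and −0.11 to 0.03. Where 1 array of a group was left, it was assumed to vary like the other groups.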

Other observations

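The tests of a common scale, of the authors' scaling and of the ribosomal RNA signal were chosen after the results were seen, while the counts over other splits of the arrays were planned.

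Single genes of other lists also changed with the AML1-ETO siRNA as the mean of both methods. NKG7, a granule membrane protein of cytotoxic cells, lay at the floor on all luciferase arrays and rose by at least 1.06 (adjusted p = 0.00108). The interferon-induced genes BST2 and IFITM2 rose by at least 0.78, with BST2 at the floor on the luciferase arrays by nucleofection, and by 0.67, and BHLHE40 and NDRG1, which respond to low oxygen, by 0.75 and 0.51. DUSP6, a phosphatase of MAP kinases, fell by 0.55, FASN, fatty acid synthase, was at −0.51 and CA2, a carbonic anhydrase, at −0.50. Adjusted p of these 7 genes lay between 0.0163 and 0.0315. Relative to untransfected cells, BST2 at −0.45, IFITM2 at −0.27 and NDRG1 at −0.20 did not pass with AML1-ETO siRNA by nucleofection, and with luciferase siRNA by nucleofection they were lower, at −1.45, a bound, −1.19 and −0.91.

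Of 43 genes of oxidative phosphorylation 14 were higher by lipid than by nucleofection, and 16 adjusted over the list alone, though the list was not called (adjusted p = 0.44). Examples were NDUFA1 at 0.86, NDUFC1 at 0.79, COX7A2 at 0.62 and NDUFB2 at 0.53, subunits of the respiratory chain, which were at 0.59, 0.52, 0.42 and 0.32 with quantile normalization. Of 32 lysosomal genes 11 were higher and 2 lower by lipid, and that list was not called either (adjusted p = 0.576). The oxidative phosphorylation and lysosomal lists were each called under 2 alternatives.

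Most genes that differed between the methods were higher by lipid. The authors' scaling to a common mean may contribute, since with arrays centred on their medians 53.9% were higher, but centring removes any shared shift whatever its source, so scaling and a real shift cannot be told apart. The ribosomal RNA signal cannot be told apart from the method either, because it followed the method. With it as a covariate 18 genes were called, while the median size over the 1841 genes went from 0.54 to 0.40 and the median SE from 0.13 to 0.25, so that the call ended partly through lost precision.

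A hypothesis is that the lipid response could be a copy of the nucleofection response at 1 smaller scale. At a fitted scale of 0.43, 5 of the 119 changed genes departed from it (4.20%), and 15 did at an unadjusted p below 0.05 (12.6%), where chance gives 5.95. The scale was fitted on the same genes, so that a copy cannot be told apart from a response that differs by gene. NFIC, S100A8 and UGDH changed more by lipid than that scale gives and TCIRG1 less, and UGDH was named after its values were seen. S100A8 lay near the floor on the luciferase arrays by nucleofection, so its nucleofection difference may be understated. The remaining gene, MS4A3, has only bounds by both methods, so that its departure is not a measured size.

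Over 100 of the 200 splits that exchange siRNAs within each method, 1, the real one, gave as many genes as the 119 called. The highest other gave 90 and differed from the real one by the exchange of 1 pair of arrays. For lipid against nucleofection 1 of 100 splits, the real one, gave 1841 and the highest other 200. A random grouping of these arrays is thus argued against for both counts. If the replicates are technical, the splits cannot exclude a difference between cultures. By lipid alone there are 10 splits, too few for a share under 0.05, and the real one gave 9 genes and the highest other 0.

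The luciferase siRNA strands as labelled, CGUACGCGGAAUACUUCGA and UCGAAGUAUUCGGCGUACG, differ from full complementarity at 1 position, C12G, counted from 1 at the 5′ end of the antisense strand.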
